A study of Mus musculus with 6 samples.

How the data were processed

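Left ventricles of mice were profiled by RNA sequencing, with 3 libraries per genotype label and 6 in all. Per the labels' protocols, polyadenylated RNA was enriched with oligo(dT) beads, prepared with an Illumina TruSeq kit, and sequenced as strand-specific read pairs on an Illumina instrument. The table deposited by the authors holds TPM per gene symbol, named as such per the file headers, with 31273 genes of which 9375 were 0 in every library. Per the submitters' processing notes, featureCounts 2.0.3, edgeR 3.40.2, GATK 4.2.6.1 and STAR-Fusion 1.11.0 were used, and a genome build mm8 is named, without the role of each. The aligner and the gene annotation are not given in the sources used here. Whether counting used the strand is not given either, so reads of overlapping or antisense genes and of near-identical gene copies cannot be assigned with certainty.

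TPM values share a fixed total, so a fall in abundant transcripts raises the values of all other genes. Library depth was estimated from the TPM values, whose low levels are whole multiples of what 1 read is worth once gene length is allowed for. With a tolerance of 0.02 reads and gene lengths searched within 50% of GENCODE M21, 12146 of 12404 tested genes (97.9%) came out whole in all libraries. In a check on 1000 genes, 999 came out whole with the found step and 0 with a wrong one. The implied length equalled that in GENCODE M21 for 1633 tested genes, so read numbers per gene are known up to a whole factor. The estimated totals were between 40500000 and 87030000 counted reads, with read ends possibly counted singly. Gene positions are those of GRCm38 with GENCODE M21 and were not used in any test.

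Groups were taken from the genotype labels. The labels do not say that the samples are separate animals beyond their title numbers, and p-values measure only the spread between these libraries. Replicate numbers 1 to 3 were assigned in order within each group and do not pair libraries, and the labels give no batch. Genes with a mean of at least 1 TPM were kept and log2(TPM + 1) was compared between groups with limma 3.58.1 in R 4.3.3 (trended moderated test, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Fold changes on this log2(TPM + 1) scale understate the change of low genes, and folds in the text are ratios of mean TPM. Exact permutation tests over 10 splits were added for Rbm20 and Atp6v0a1. A second scaling divided each library by its median ratio to the geometric mean over genes, and list counts are given under both scalings.

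Before the data were examined, 36 gene lists were fixed, 8 of them main lists, which cover heart function, metabolism, stress and markers of other cell types. They were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, using statmod 1.5.0. The rule for named genes, fixed at the same time, took Rbm20 and Atp6v0a1 first. It added the 8 largest increases and 8 largest decreases of the log2(TPM + 1) difference. These were taken among called genes with non-overlapping groups and a gene name that is not a placeholder. It also took the 4 members with the smallest p of each main list or list past the threshold. Another 16 genes were singled out after their values were seen, and the text says so where they appear. List members without a value in the table were not analysed here. The values of 1 gene that the rule names are not reported here.

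The alternatives were other pseudocounts, filters and scalings, removal of mitochondrially encoded genes, other limma settings, and each library left out in turn. Voom from limma on the recovered whole reads, and leaving out libraries after rescaling, were added after the data had been seen. The scripts were tested on simulated libraries. In a simulated overexpression against control comparison of 11818 genes, 97.9% of genes changed 2-fold and 100% of genes changed 4-fold were recovered. In it 21 of 229 calls were of unchanged genes, and the list that was raised was the only 1 called by preset camera. Camera with an estimated correlation and fry were not run on simulated libraries. All simulations drew genes independently with a dispersion of 0.02, so false list calls from genes that move together could not appear. With mitochondrially encoded RNA alone multiplied by 0.6 (11996 genes), the median log2 difference was 0.33 in TPM and -0.001 after rescaling, with 4647 and 1 genes called higher. With no change (11713 genes), 3 genes were called. Summaries and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Splicing, fusions and variants were not analysed here.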

Results

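Polyadenylated RNA of mouse left ventricle was sequenced in 6 libraries. The labels gave 3 libraries a control genotype and 3 libraries cardiomyocyte-specific overexpression of RBM20, a splicing regulator of the heart. Expression was given as TPM, a length-corrected share of all transcripts, for 31273 gene symbols, of which 12404 reached a mean of 1 TPM and were tested. Library size was estimated from the steps between low values at 47860000, 68520000 and 40500000 counted reads for control replicates 1 to 3, and at 52710000, 49200000 and 87030000 for overexpression replicates 1 to 3. Genes above 0 numbered 17531, 18085 and 17218 in the control libraries and 18403, 18406 and 19702 in the overexpression libraries. Mitochondrially encoded transcripts made up 49.7% ± 2.0 of the TPM in the control group and 38.7% ± 2.21 in the overexpression group (SD, n = 3 each). Pearson correlations of log2 values across genes, which are not independent replicates, were 0.975 to 0.992 within groups and 0.899 to 0.933 between them.

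The first question was whether the overexpressed gene followed the labels. Rbm20 stood at 74.9, 90.9 and 79.5 TPM in the control libraries and at 321, 913 and 907 TPM in overexpression replicates 1, 2 and 3. The group means were 81.8 ± 8.21 and 714 ± 340.2 TPM (SD, n = 3 each), an 8.73-fold increase that was higher in 3 of 3 overexpression libraries. The limma log2 difference was 2.96 (SE 0.355, adjusted p = 0.000182) and an exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 allows. Rbm20 lies on chromosome 19 at 53677306 to 53867080 on the plus strand of GRCm38 (GENCODE M21, ENSMUSG00000043639.15). Esr1, the estrogen receptor gene, followed the same split, at 0.415, 0.234 and 0.301 TPM in the control libraries against 217.8, 52.98 and 198.8 TPM. Sex did not: overexpression replicate 1 had the Y-linked Ddx3y at 88.1 TPM and Xist at 0.02 TPM, whereas the other 5 libraries had Xist between 34.4 and 62.6 TPM and Ddx3y at 0. The sample titles use cki for the control libraries and cre for the overexpression libraries, and groups were taken from the genotype labels, not from these abbreviations.

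**Figure D1:**
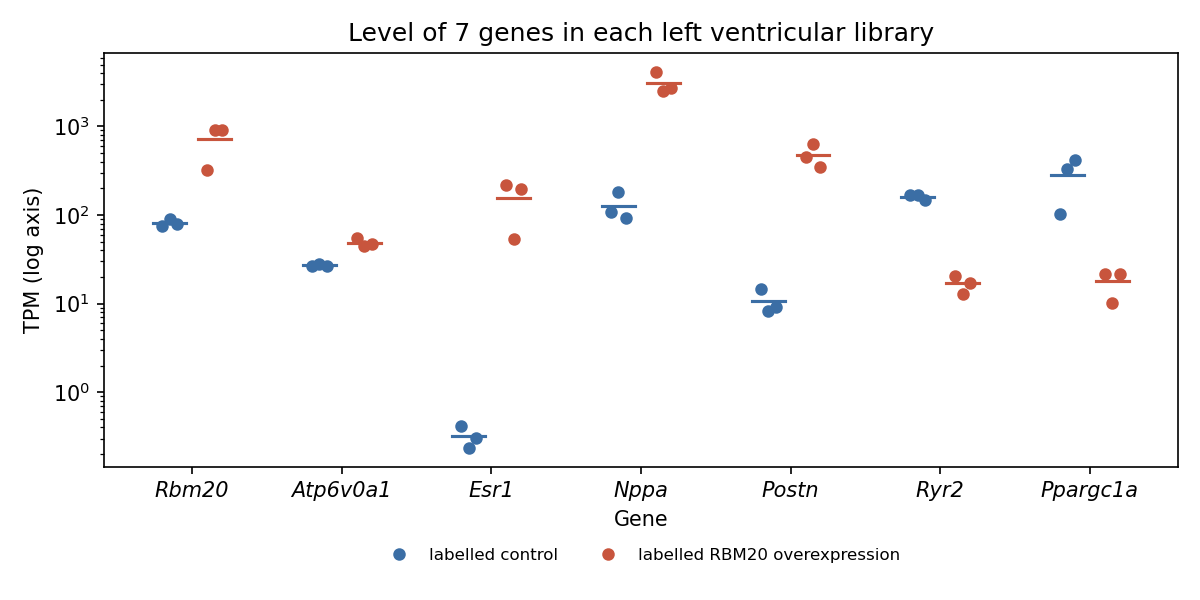
TPM per library of selected genes on a log axis, with each point a library and each bar a group mean (n = 3 per group). Rbm20 was between 74.9 and 90.9 TPM in the control libraries and between 321 and 913 TPM in the overexpression libraries.

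Atp6v0a1 encodes a membrane subunit of the vacuolar proton pump, and its splicing is the subject of the study. Its total level was 27.0 ± 0.814 TPM in the control group and 48.7 ± 5.12 TPM in the overexpression group (SD, n = 3 each), 1.81-fold higher, with 3 of 3 overexpression libraries above all control libraries. The limma log2 difference was 0.83 (SE 0.107, adjusted p = 0.000263), and the exact permutation p was 0.1, again the smallest possible. After rescaling of the libraries by median of ratios the difference was 0.22 (SE 0.112) and no longer passed the test (adjusted p = 0.155). The gene lies on chromosome 11 at 101009452 to 101063719 on the plus strand of GRCm38 (GENCODE M21, ENSMUSG00000019302.16). Exon use was not analysed here, and gene totals cannot show it. With a fixed length per gene, a change in exon use can also move TPM without a change in transcript number.

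The main comparison asked which genes differed between overexpression and control ventricles. Called higher in TPM and after rescaling were 20 of 22 fetal and hypertrophic cardiac genes and 38 of 43 matrix genes. So were 17 of 20 macrophage markers and 23 of 24 cell cycle genes. Only 9 of these 24 cell cycle genes had a control mean of at least 1 TPM. The others passed the filter through the overexpression group, which favours increases. Called lower under both were 20 of 36 calcium handling genes, 30 of 38 fatty acid oxidation genes and 41 of 44 nuclear oxidative phosphorylation genes. Rescaling moved differences downward, and 0 genes called lower in TPM lost the call, so for decreases the second scaling is no separate check. None of these 7 lists passed camera with an estimated correlation (adjusted p = 0.222 to 0.695). The simulations ran camera only with the preset correlation, so whether the estimated correlation leaves power to call a raised list is not known here. A list that it did not call is thus not shown to be unchanged. Ranked by the log2(TPM + 1) difference, the 8 largest increases were in Tnnt3, Esr1, Sprr1a, Timp1, Postn, Acta1, Cxcr6 and Mybpc2. Ratios of mean TPM, used for folds in the text, give another order. Tnnt3, the troponin T of fast skeletal muscle, rose from 0.686 ± 0.0383 to 264 ± 53.9 TPM, and Acta1, skeletal muscle actin, from 159 ± 86.8 to 5524 ± 171 TPM (SD, n = 3 each). Postn, a matrix protein of activated fibroblasts, rose 44.8-fold to 478 ± 150.1 TPM, and Timp1, an inhibitor of matrix metalloproteinases, rose 76.1-fold to 202 ± 97.4 TPM. Sprr1a was listed at 0, 0 and 0.143 TPM in the control libraries and at 155, 93.9 and 48.1 TPM in the overexpression libraries. Cxcr6, a chemokine receptor, rose to 50.7 ± 19.3 TPM and Mybpc2, fast skeletal myosin-binding protein C, to 215 ± 46.6 TPM.

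By the same log2 difference, the 8 largest decreases were in Mylk4, Kcnip2, Asb14, Ppargc1a, Pxmp2, Lsmem1, Ryr2 and Ces1d. Mylk4, a myosin light chain kinase, went from 131 ± 17.7 to 5.20 ± 1.84 TPM (log2 difference -4.45, SE 0.201). Kcnip2, the accessory subunit of the transient outward potassium channel, went from 93.3 ± 9.88 to 4.66 ± 2.63 TPM, and Ryr2, the calcium release channel of the sarcoplasmic reticulum, from 161 ± 11.3 to 16.9 ± 3.97 TPM. Ppargc1a, a coactivator that drives mitochondrial biogenesis, went from 285 ± 162 to 17.8 ± 6.55 TPM (SD, n = 3 each). The adjusted limma p-values of these 16 genes lay between 1.36e-07 for Tnnt3 and 0.000263 for Ppargc1a. All 16 passed the test after rescaling as well, which for the 8 decreases is no separate check because rescaling moved differences downward.

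In deposited TPM 8443 of 12404 genes (68.1%) passed an adjusted p of 0.05, 7316 higher and 1127 lower with overexpression, and the median log2 difference over all genes was 0.55. Rescaling by median of ratios brought that median to 0.01 and gave 5730 genes, 2756 higher and 2974 lower. Higher under both scalings were 2756 genes and lower under both were 1127. A further 4436 genes were higher in TPM and not called after rescaling, 124 turned from higher to lower, and 1723 were lower only after rescaling. A log2 difference of at least 1 under both scalings was seen in 743 genes that rose and 375 that fell. Because rescaling moved differences downward, the rescaled values set the limit for rises and TPM set it for falls. The counts of rises and falls under both scalings, 2756 and 1127 as well as 743 and 375, are therefore not on an equal footing. In deposited TPM the 2 groups did not overlap in 8988 genes (72.5%), against 10% by chance for a single gene. The rescaling factors alone were 0.78 to 0.845 in control and 1.157 to 1.334 in overexpression libraries. A shift shared by many genes therefore separates the groups too, and 72.5% does not measure change gene by gene. Because the scaling moved the median of all genes, counts for each gene list are given in TPM and after rescaling. The gene list test, camera, compares a list with all other genes, so its direction is relative to those genes and not to no change. That direction need not follow the median log2 difference of a list. Immediate early genes, atrial cardiomyocyte markers and fibroblast markers had medians above 0.55, yet camera placed them below other genes without calling them. The lists called with the preset correlation had medians on the side of 0.55 that camera gave. With its preset correlation 19 of 36 lists passed, 11 above and 8 below other genes. Of the 10 splits of the libraries 4, the real split among them, reached that number. With an estimated correlation camera called 0 lists (adjusted p 0.222 to 0.979, 4 lists at an unadjusted p under 0.05), and fry called 27. Fry asks whether a list differs from no change, not from other genes, and it was run on deposited TPM. Lists that only share the shift of the median can therefore pass it. Autophagy genes had a fry adjusted p of 0.0057 and a camera adjusted p of 0.919. After rescaling preset camera called 16 lists, 14 of them among the 19.

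Fetal and hypertrophic cardiac genes rose together. Of 22 tested members 20 were higher and 1 was lower, with the same counts adjusted over the list alone, and 20 were higher and 2 lower after rescaling. Ankrd1, a stress-responsive titin-binding protein, rose from 878 ± 135 to 7755 ± 232 TPM, Xirp2 from 75.5 ± 11.6 to 683 ± 93.0 TPM and Synpo2l from 61.5 ± 11.2 to 475 ± 49.1 TPM (SD, n = 3 each). Among genes singled out after their values were seen, the natriuretic peptide genes Nppa and Nppb rose 24.6-fold and 8.36-fold, to 3122 ± 882 and 4385 ± 286 TPM, and Myh7, the slow myosin heavy chain, rose 5.47-fold. Fhl2 was the member that fell in TPM, from 1735 ± 81.0 to 551 ± 27.4 TPM, and it too was singled out after its values were seen. The median log2 difference of the list was 2.84 (camera adjusted p = 8.04e-05, and adjusted p = 0.353 with an estimated correlation).

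Genes of the adult sarcomere and Z-disc went both ways. Of 32 tested members 13 were higher and 9 lower, with the same counts adjusted over the list alone, and 8 were higher and 18 lower after rescaling. Flnc, which crosslinks actin at the Z-disc, rose from 53.2 ± 9.52 to 321 ± 51.1 TPM, Myot rose 5.29-fold and Csrp3 rose 3.02-fold to 2132 ± 210 TPM (SD, n = 3 each). Myom2, an M-band protein, fell from 546 ± 77.5 to 127 ± 18.3 TPM. Titin, singled out after its values were seen, was at 73.8 ± 5.36 and 71.6 ± 12.4 TPM, and its gene Ttn was not called in TPM (log2 difference -0.05, adjusted p = 0.73) but lower after rescaling (-0.67, adjusted p = 0.00511). The list median was 0.03 and its mean 0.34, while camera placed it below other genes (adjusted p = 0.0342, and adjusted p = 0.695 with an estimated correlation). That call also ended after rescaling (adjusted p = 0.13), under quantile normalization (0.533), with voom (0.159) and with no filter (0.233). It ended as well without control replicate 1 (0.0572), overexpression replicate 1 (0.0835) or overexpression replicate 2 (0.0861).

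More calcium handling and excitation genes fell than rose. Of 36 tested members 20 were lower and 2 higher, with the same counts adjusted over the list alone, and 24 were lower and 0 higher after rescaling. Beside Ryr2, the L-type calcium channel gene Cacna1c fell from 32.8 ± 2.69 to 3.98 ± 0.40 TPM, phospholamban (Pln) from 1280 ± 115 to 183 ± 37.8 TPM and Kcnj3 from 28.6 ± 2.99 to 4.95 ± 0.937 TPM (SD, n = 3 each). Atp2a2, the calcium pump of the sarcoplasmic reticulum, was singled out after its values were seen and fell from 3834 ± 201 to 1529 ± 327 TPM. The list had a median log2 difference of -0.60 (camera adjusted p = 2.43e-17, and adjusted p = 0.222 with an estimated correlation).

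Extracellular matrix and fibrosis genes rose. Of 43 tested members 40 were higher and 0 lower, with the same counts adjusted over the list alone, and 38 were higher and 1 lower after rescaling. Col8a1, a short-chain collagen, rose from 11.8 ± 3.13 to 184 ± 39.0 TPM, and the collagen-crosslinking enzymes Loxl1 and Loxl2 rose 9.31-fold and 12.5-fold (n = 3 each). The median log2 difference was 2.51 (camera adjusted p = 4.74e-08, and adjusted p = 0.615 with an estimated correlation). Of 18 fibroblast markers 11 were higher and 3 lower, with the same counts adjusted over the list alone, and 7 were higher and 7 lower after rescaling (camera adjusted p = 0.661).

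Macrophage markers rose in the same libraries. All 20 tested members were higher, also adjusted over the list alone, and 17 stayed higher after rescaling. Fcer1g rose from 15.49 ± 1.014 to 60.2 ± 14.4 TPM, Cd68 from 8.82 ± 1.72 to 38.9 ± 8.60 TPM, the complement gene C1qc from 48.7 ± 5.93 to 136 ± 24.5 TPM and Mrc1 from 19.3 ± 3.61 to 64.5 ± 13.9 TPM (SD, n = 3 each). The list had a median log2 difference of 1.74 (camera adjusted p = 0.00306, and adjusted p = 0.695 with an estimated correlation). Of 22 lymphocyte and neutrophil markers 5 reached the expression filter, 4 of them with a control mean of at least 1 TPM. These 5 were higher, also adjusted over the list alone, with 2 higher after rescaling (camera adjusted p = 0.299). Endothelial markers were higher in 4 of 20 and lower in 0, with the same counts adjusted over the list alone, and after rescaling 2 were higher and 6 lower (camera adjusted p = 0.376). Pericyte and smooth muscle markers were higher in 4 of 14 and lower in 1, with the same counts adjusted over the list alone, and after rescaling 2 were higher and 8 lower (camera adjusted p = 0.149).

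Interferon response genes were higher in 26 of 29 tested members and lower in 0 (27 and 0 adjusted over the list alone), with 18 higher after rescaling. Ifi27l2a rose from 73.4 ± 9.36 to 269 ± 13.7 TPM, Ifit2 rose 2.88-fold and Isg15 4.16-fold (n = 3 each). As a group they had a camera adjusted p of 0.00544, and adjusted p = 0.695 with an estimated correlation. Cytokine and acute inflammation genes were higher in 17 of 22 and lower in 0, with the same counts adjusted over the list alone, and 12 were higher and 1 lower after rescaling (camera adjusted p = 0.118 in TPM and 0.00609 after rescaling, where adjusted p = 0.492 with an estimated correlation). Cell cycle genes were higher in all 24 tested members, also adjusted over the list alone, and in 23 after rescaling, although 9 of the 24 had a control mean of at least 1 TPM. The replication helicase subunit Mcm6 rose from 2.70 ± 0.712 to 18.7 ± 4.82 TPM, and Top2a and Mki67 rose to 10.6 ± 4.91 and 7.22 ± 2.98 TPM from below 1 TPM (SD, n = 3 each). The camera adjusted p of the cell cycle list was 0.000237, and adjusted p = 0.695 with an estimated correlation.

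**Figure D2:**
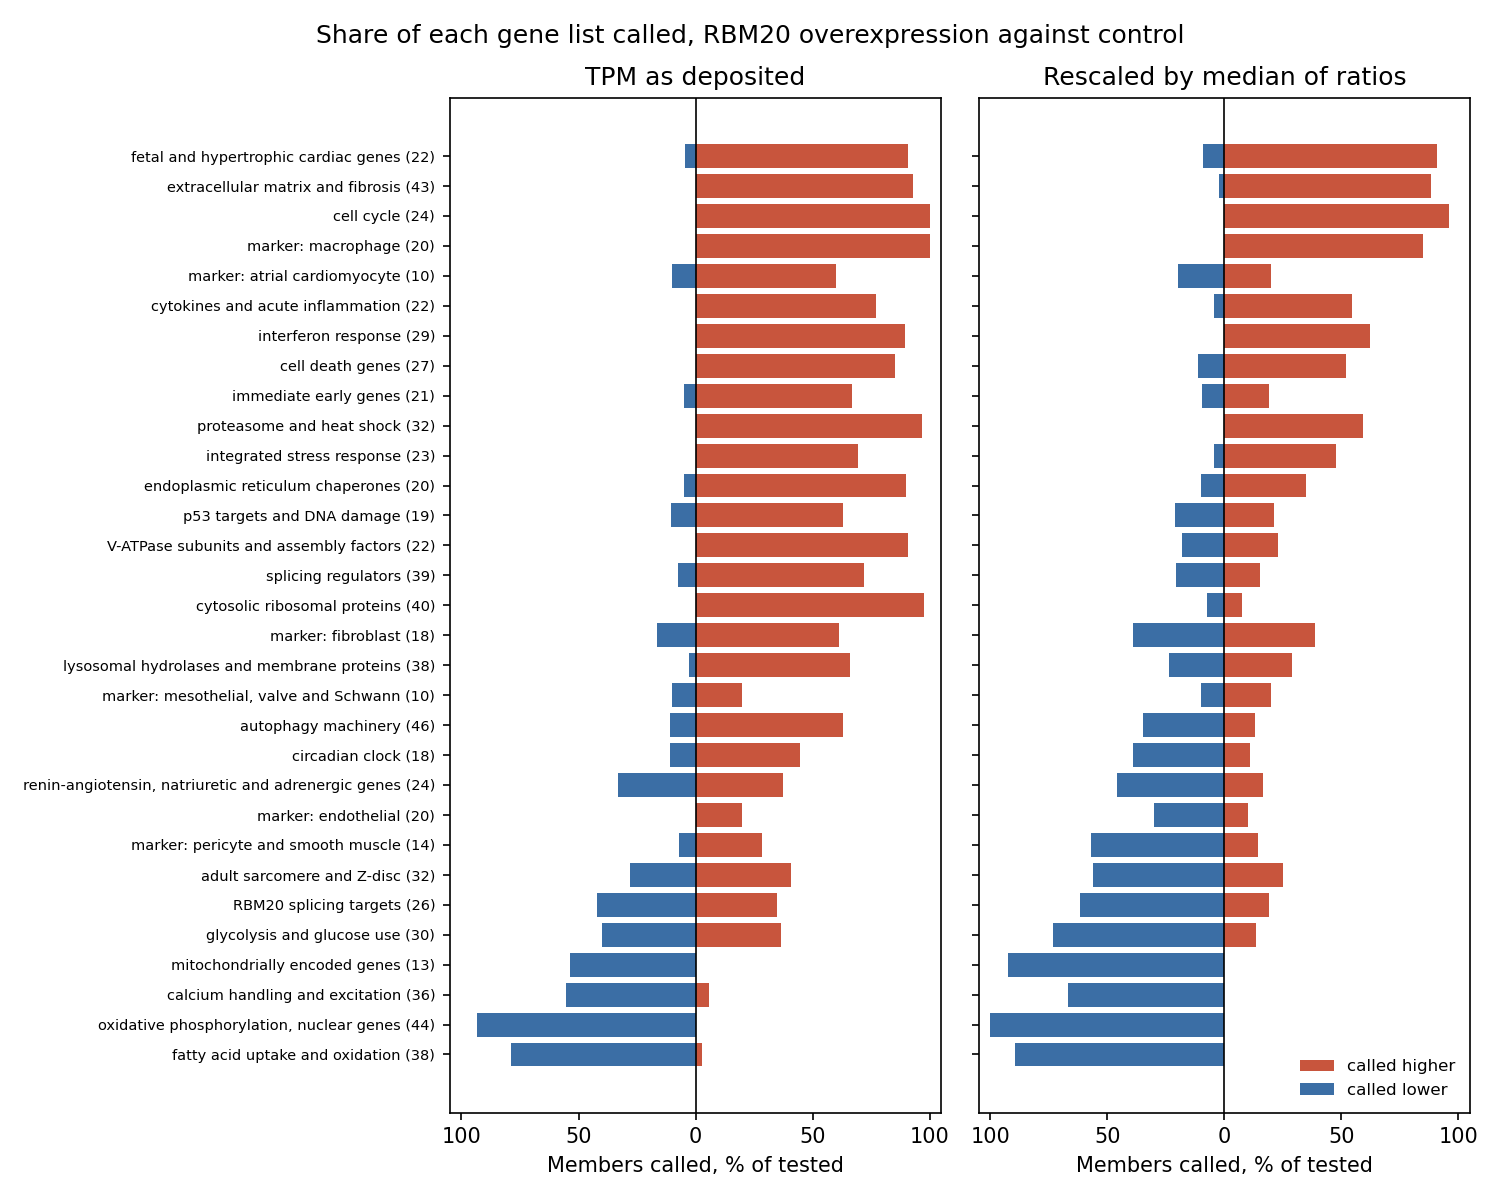
Percentage of tested members called higher or lower with overexpression by limma (adjusted p under 0.05), for each gene list with at least 10 tested members, in deposited TPM and after rescaling by median of ratios. Nuclear oxidative phosphorylation genes were lower in 41 of 44 members in TPM and in 44 after rescaling, and matrix genes were higher in 40 of 43 and in 38.

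Of 44 nuclear genes of oxidative phosphorylation 41 were lower and 0 higher (42 and 0 adjusted over the list alone), and all 44 were lower after rescaling. Cox7a1, the heart and muscle form of a cytochrome oxidase subunit, fell from 1197 ± 91.5 to 312 ± 33.2 TPM, and the ATP synthase gene Atp5a1 from 2695 ± 94.8 to 1551 ± 43.2 TPM (SD, n = 3 each). The median log2 difference was -0.58 (camera adjusted p = 1.17e-39, and adjusted p = 0.334 with an estimated correlation). Of 13 mitochondrially encoded genes 7 were lower and 0 higher (6 and 0 adjusted over the list alone), and 12 were lower after rescaling. mt-Co3 went from 8800 ± 2128 to 5305 ± 648 TPM and mt-Co1 from 151000 ± 8755 to 113200 ± 8186 TPM (SD, n = 3 each). Camera gave this list an adjusted p of 4.74e-08, and adjusted p = 0.344 with an estimated correlation, and the call also ended under quantile normalization (adjusted p = 0.318). The calls of mt-Nd2, mt-Nd1 and mt-Co1 ended without overexpression replicate 2, at adjusted p of 0.0589, 0.0754 and 0.135.

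Fatty acid uptake and oxidation genes were lower in 30 of 38 and higher in 1 (31 and 1 adjusted over the list alone), with 34 lower and 0 higher after rescaling. Cpt2, of the carnitine shuttle, fell from 104 ± 2.24 to 38.5 ± 2.02 TPM, the beta-oxidation genes Hadha and Hadhb to 229 ± 16.5 and 251 ± 27.8 TPM from 557 ± 12.7 and 700.4 ± 13.0 TPM, and the lipid droplet gene Plin5 to 12.0 ± 0.847 from 59.4 ± 9.68 TPM (SD, n = 3 each). The list had a median log2 difference of -1.04 (camera adjusted p = 5.37e-32, and adjusted p = 0.292 with an estimated correlation). Glycolysis and glucose use genes divided, with 11 of 30 higher and 12 lower, the same counts adjusted over the list alone, and 4 higher and 22 lower after rescaling. Pfkp, the platelet form of phosphofructokinase, rose 3.999-fold to 43.6 ± 8.87 TPM, while Pfkm, the muscle form, fell from 502 ± 23.4 to 212 ± 32.6 TPM (SD, n = 3 each). Slc2a4, the insulin-responsive glucose transporter, fell from 197 ± 9.99 to 82.5 ± 6.24 TPM (SD, n = 3 each). In the camera test the adjusted p was 1.53e-05, and adjusted p = 0.575 with an estimated correlation.

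The design text places the proton pump and autophagy at the centre of the study. Of 22 genes for subunits and assembly factors of the vacuolar ATPase 20 were higher and 0 lower, with the same counts adjusted over the list alone, but after rescaling 5 were higher and 4 lower. Atp6ap2 rose under both scalings, from 21.2 ± 0.347 to 50.6 ± 5.09 TPM (SD, n = 3 each), whereas Atp6ap1, 1.71-fold higher in TPM, lost its call after rescaling (adjusted p = 0.19). Tested with camera, the list had an adjusted p of 0.0109, and adjusted p = 0.695 with an estimated correlation. After rescaling the V-ATPase list did not pass camera (adjusted p = 0.325). Autophagy genes were higher in 29 of 46 and lower in 5 (30 and 5 adjusted over the list alone), with 6 higher and 16 lower after rescaling (camera adjusted p = 0.919). Sqstm1, the autophagy receptor p62, rose from 252 ± 19.7 to 600.5 ± 49.8 TPM and Atg10 fell from 21.3 ± 0.807 to 5.70 ± 1.20 TPM (SD, n = 3 each). Map1lc3b, singled out after its values were seen, was at 99.6 ± 2.11 and 95.8 ± 13.4 TPM, not called in TPM (adjusted p = 0.622) and lower after rescaling (log2 difference -0.69, adjusted p = 0.00142). Lysosomal hydrolases and membrane proteins were higher in 25 of 38 and lower in 1, with the same counts adjusted over the list alone, and 11 were higher and 9 lower after rescaling (camera adjusted p = 0.352). With no filter camera called the lysosomal list (adjusted p = 0.0163). Cd63 rose from 49.6 ± 0.338 to 139 ± 22.2 TPM and the protease gene Ctsz from 22.7 ± 3.44 to 75.2 ± 10.7 TPM (SD, n = 3 each).

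**Figure D3:**
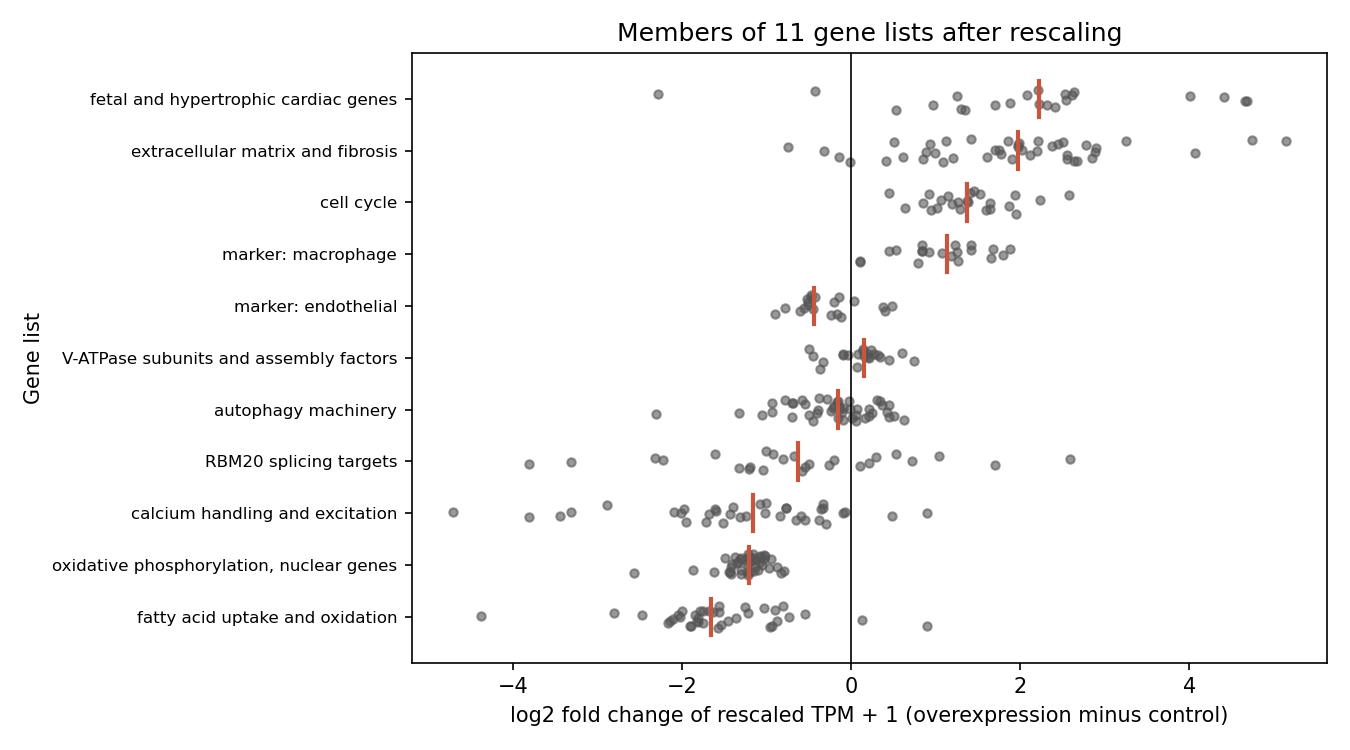
Log2 difference of each tested member of selected gene lists, overexpression minus control, after rescaling by median of ratios, with each point a gene and each vertical mark the list median. Matrix genes had a median of 1.97, calcium handling genes of -1.16 and nuclear oxidative phosphorylation genes of -1.21.

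Known splicing targets of RBM20 also differed in their gene-level TPM, which a change in exon use alone could move. Of 26 tested members 9 were higher and 11 lower (10 and 11 adjusted over the list alone), and 5 were higher and 16 lower after rescaling. Rtn4 rose from 39.1 ± 3.66 to 375 ± 70.8 TPM and Pdlim3 from 16.7 ± 2.52 to 86.2 ± 1.33 TPM, while Ryr2 and Cacna1c, which belong to this list too, fell as given above (SD, n = 3 each). Camk2d, a cardiac calmodulin kinase singled out after its values were seen, fell from 54.4 ± 2.94 to 26.7 ± 0.46 TPM (SD, n = 3 each). The median log2 difference was 0.00 and camera placed the list below other genes (adjusted p = 0.000692, and adjusted p = 0.575 with an estimated correlation). Quantile normalization and voom also ended that call (adjusted p = 0.144 and 0.136). Splicing regulators were higher in 28 of 39 and lower in 3, with the same counts adjusted over the list alone, and 6 were higher and 8 lower after rescaling (camera adjusted p = 0.287).

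Cytosolic ribosomal protein genes were higher in 39 of 40 and lower in 0, with the same counts adjusted over the list alone, but after rescaling 3 were higher and 3 lower. Rpl3 rose under both scalings, from 144.1 ± 19.99 to 470.2 ± 48.1 TPM, while Rpl7a at 524 ± 30.8 and 909.8 ± 64.3 TPM lost its call after rescaling (SD, n = 3 each). The camera adjusted p of this list was 0.000191, and adjusted p = 0.695 with an estimated correlation. After rescaling camera did not call the ribosomal list (adjusted p = 0.336). Proteasome and heat shock genes were higher in 31 of 32 and lower in 0, with the same counts adjusted over the list alone, and in 19 after rescaling. Psma5 rose from 61.3 ± 4.01 to 184 ± 17.0 TPM and Psmd11 from 42.1 ± 3.02 to 107 ± 4.54 TPM (SD, n = 3 each). For these genes camera returned an adjusted p of 6.14e-06, and adjusted p = 0.615 with an estimated correlation. Endoplasmic reticulum chaperones were higher in 18 of 20 and lower in 1, with the same counts adjusted over the list alone, and 7 were higher and 2 lower after rescaling. Pdia4, a disulfide isomerase, rose from 15.2 ± 1.82 to 45.9 ± 7.96 TPM (SD, n = 3 each). As a group they had a camera adjusted p of 0.0353, and adjusted p = 0.695 with an estimated correlation. The chaperone list did not pass camera after rescaling (adjusted p = 0.082), with a filter of mean TPM at least 5 (0.0847) or with voom (0.12). Nor did it pass without control replicate 1 (0.0572) or overexpression replicate 1 (0.0531).

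Cell death genes were higher in 23 of 27 and lower in 0 (25 and 0 adjusted over the list alone), with 14 higher and 3 lower after rescaling. Bik, a pro-apoptotic BCL2 relative, rose from 2.96 ± 0.302 to 14.8 ± 1.68 TPM and Acsl4, an acyl-CoA synthetase, from 9.40 ± 1.14 to 26.1 ± 0.807 TPM (SD, n = 3 each). In the camera test the adjusted p was 0.0109, and adjusted p = 0.695 with an estimated correlation. Renin-angiotensin, natriuretic and adrenergic genes went both ways, with 9 of 24 higher and 8 lower, the same counts adjusted over the list alone, and 4 higher and 11 lower after rescaling. Ace rose from 19.2 ± 2.38 to 76.4 ± 14.8 TPM, and Corin, the protease that activates atrial natriuretic peptide, fell from 83.3 ± 16.1 to 24.4 ± 4.23 TPM (SD, n = 3 each). Their median was 0.19 while camera placed them below other genes (adjusted p = 0.0107, and adjusted p = 0.37 with an estimated correlation). After rescaling camera did not call them (adjusted p = 0.0614). Of 14 skeletal muscle markers 4 reached the expression filter, 3 of them with a control mean of at least 1 TPM, and these 4 were higher under both scalings and adjusted over the list alone, among them Casq1, which rose from 7.78 ± 1.11 to 124 ± 9.11 TPM (SD, n = 3 each). Tested with camera, the list had an adjusted p of 0.0109, and adjusted p = 0.353 with an estimated correlation. With no filter the call ended (adjusted p = 0.619).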

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

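Voom on recovered reads and the libraries left out after rescaling were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because the labels give the groups no shared replicate numbers. The direction split depended on scaling: rescaling by median of ratios gave 2756 higher and 2974 lower, quantile normalization 2963 and 2816, and voom 5362 genes, 2564 higher and 2798 lower. Without mitochondrially encoded genes most calls were still higher, with 5382 higher and 1796 lower. A minimum log2 difference of 1 left 2831 genes, 2456 higher and 375 lower. Atp6v0a1 kept its direction but lost its call under rescaling (0.22, adjusted p = 0.155), quantile normalization (0.31, adjusted p = 0.0569) and voom (0.21, adjusted p = 0.164); over all alternatives its adjusted p ranged from 0.000174 to 0.164. These scalings remove the shift of the median, and the cause of that shift is weighed below. Camera with an estimated correlation called 0 lists (4 at an unadjusted p under 0.05) and preset camera 19. Fry, which tests against no change and not against other genes, called 27. With each library left out in turn, called genes ranged from 7225 to 8283 (higher 6198 to 7212, lower 950 to 1088), and after rescaling from 4414 to 5478 (higher 2045 to 2639, lower 2369 to 2839). Rbm20 ranged from 2.71 to 3.47, Atp6v0a1 from 0.74 to 0.89 and lists from 17 to 20. Without overexpression replicate 1, the library with Y-linked expression, 7904 genes were called, and 5227 after rescaling. Camera's direction turned for 3 lists that it did not call under that setting: autophagy with no filter (median 0.45, adjusted p = 0.278), lysosome after rescaling (-0.054, adjusted p = 0.943) and sarcomere after quantile normalization (-0.018, adjusted p = 0.533). Without overexpression replicate 1, Ttn (0.095, adjusted p = 0.428; range over libraries left out -0.134 to 0.095) and Map1lc3b (0.045, adjusted p = 0.686; -0.156 to 0.045), neither called in TPM, changed sign. The cause of these turns was not tested. Called lists lost their camera call in 23 further cases, mostly the sarcomere, chaperone, V-ATPase, ribosomal and renin-angiotensin lists, and also RBM20 targets under quantile normalization and voom, mitochondrially encoded genes under quantile normalization and skeletal muscle markers with no filter. Other lists gained a call: 20 were called with no filter, 16 of them among the 19, and 17 with voom, 14 of them among the 19. The lysosomal list was among those gained with no filter (camera adjusted p = 0.0163). Of the other values for named genes 1805 kept their direction and their status, called or not called, 34 lost the call and 7 gained it. Depth limits genes near 0, such as Sprr1a at 0, 0 and 0.143 TPM in the control libraries, and TPM rests on gene lengths that are not given.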

Other observations

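All tests of explanations in this part were chosen after the results were seen. Integrated stress response genes were higher in 16 of 23 tested members and lower in 0, with the same counts adjusted over the list alone, and 11 were higher and 1 lower after rescaling (camera adjusted p = 0.0936 in TPM and 0.0092 after rescaling, where adjusted p = 0.414 with an estimated correlation). Immediate early genes were higher in 14 of 21 and lower in 1, with the same counts adjusted over the list alone, and 4 were higher and 2 lower after rescaling (camera adjusted p = 0.936). Circadian clock genes were higher in 8 of 18 and lower in 2 (7 and 2 adjusted over the list alone), with 2 higher and 7 lower after rescaling (camera adjusted p = 0.269). Of 19 p53 targets and DNA damage genes, 12 were higher and 2 lower, the same adjusted over the list alone, and 4 were higher and 4 lower after rescaling (camera adjusted p = 0.929 in TPM and 0.297 after rescaling). Among them, singled out after their values were seen, Phlda3, Mdm2, Eda2r and Bax were higher under both scalings (4.99-fold, 2.85-fold, 7.44-fold and 2.46-fold in TPM), and Ccng1 and Sesn1 were lower under both (log2 differences of -0.52 and -0.65 in TPM, -1.14 and -1.27 after rescaling). Cdkn1a, singled out in the same way, was higher in TPM (1.39, adjusted p = 0.0161) and not called after rescaling (adjusted p = 0.181). The TPM call of Sesn1 ended without control replicate 1, 2 or 3 (adjusted p = 0.109, 0.0564 and 0.105), and that of Cdkn1a without control replicate 3 or overexpression replicate 2 or 3 (0.0612, 0.0749 and 0.0506). Myoglobin (Mb), singled out after its values were seen, fell from 10230 ± 377 to 3590 ± 700 TPM (SD, n = 3 each, limma adjusted p = 4.84e-05).

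Erythroid markers were higher in 1 of 8 and lower in 0, with the same counts adjusted over the list alone, and 0 were called after rescaling (camera adjusted p = 0.269). Mesothelial, valve and Schwann cell markers were higher in 2 of 10 and lower in 1, with the same counts adjusted over the list alone and after rescaling (camera adjusted p = 0.287). Atrial cardiomyocyte markers were higher in 6 of 10 and lower in 1, with the same counts adjusted over the list alone, and 2 were higher and 2 lower after rescaling (camera adjusted p = 0.815). Of 4 tested adipocyte markers 2 were higher and 0 lower under both scalings and adjusted over the list alone (camera adjusted p = 0.472). Of 4 tested sex chromosome genes limma called 0, also adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.408), with the 1 library that had Y-linked expression in the overexpression group.

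Most tested genes were higher in TPM with overexpression, with a median log2 difference of 0.55. Removing the mitochondrially encoded genes, whose share fell, left a median of 0.33, and removing the 100 most abundant genes left 0.23, so neither accounts for the whole shift. Gene length does not either, since the lowest of the medians over 5 length groups was 0.45 and the highest 0.59. Of the 10 splits of the libraries 1, the real one, gave as many genes (8443, highest other 0; after rescaling also 1, with 5730 and 0), but 10 splits are too few for a share under 0.05. For gene lists 4 of 10 splits, the real split among them, gave at least the real 19 (highest other 22). The other splits mix the labels and keep part of their difference in every gene, so they are no reference without change. They therefore give the preset-correlation list calls no backing and cannot weigh them, while camera with an estimated correlation called 0 lists. What accounts for the remaining shift stays open, and a fall spread over more than the 100 most abundant genes was not tested.

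Matrix and macrophage genes rose while endothelial markers did not rise to the same degree. A lower share of cardiomyocyte RNA would raise markers of all other cell types alike, but macrophage markers exceeded endothelial markers by a median log2 difference of 1.56 (bootstrap 95% interval over genes 1.06 to 1.72). Of the 20 macrophage markers, 18 were at 1 TPM or more in control ventricles and 1 is also in another list. More fibroblasts with unchanged expression would raise matrix genes and fibroblast markers alike, but matrix genes exceeded them by 1.86 (1.22 to 2.67). Of the 43 matrix genes, 38 were at 1 TPM or more in control ventricles, as were all 18 fibroblast markers. The other matrix genes passed the filter through the overexpression group, which favours increases. Both intervals resample genes that move together, with estimated correlations of 0.781 for macrophage markers and 0.433 for matrix genes. They may thus be too narrow, and they carry no spread between libraries. A fall of endothelial RNA together with cardiomyocyte RNA was not tested. Fibroblast activation and more or altered macrophages may account for the pattern and remain open as hypotheses, because cell numbers were not measured. Counts of these cells in both groups would be needed to decide. Overexpression is the difference the design names. Cre or tamoxifen may differ between the groups too, as the Esr1 values below leave possible, and could underlie the same pattern.

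Esr1 was among the largest increases, with a ratio of mean TPM of 495, which equal expression of the same Cre transgene in both groups would not give. Inducible Cre proteins carry estrogen receptor sequence, and the design names a tamoxifen-inducible model, so reads from such a transgene may be counted as Esr1; this was not tested on sequence. If so, effects of Cre or tamoxifen cannot be told apart from those of RBM20 by these groups. The p53 targets and DNA damage genes had a median of 0.26 after rescaling, with members going both ways, which leaves DNA damage from Cre open.

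Overexpression replicate 1 had 321 TPM of Rbm20, and its Rbm20 increase in TPM, not on the log2 scale, was 0.29 of the mean increase in the other 2 overexpression libraries. Across 2409 genes chosen on those other libraries, its change was a median 0.94 of theirs (quartiles 0.76 and 1.13). The corresponding medians were 1.15 for replicate 2 and 0.75 for replicate 3, with Rbm20 shares of 1.56 and 1.54. All these shares use the same 3 control libraries, and a control library set against the other controls had medians of 0.031, 0.038 and -0.024. The overexpression medians had the order of the rescaling factors, 1.334, 1.243 and 1.157 for replicates 2, 1 and 3. A shift shared by many genes may therefore enter them, and no relation between Rbm20 level and response can be read from them. Replicate 1 is also the 1 library with Y-linked expression.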
